A study of Mus musculus with 8 samples.

How the data were processed

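Paired B-cell receptor sequencing was analysed in 8 libraries of mouse spleen germinal-centre B cells, 4 WT and 4 Dtx1 knockout (KO), taken on day 10 after immunization. Per the labels' protocols, cells were enriched with peanut agglutinin beads, sorted, and prepared with a droplet single-cell kit and a mouse B-cell receptor amplification kit. The immunogen, the sort gates, the number of mice and how cells were divided among libraries are not given in the sources used here. Per the submitters' processing notes, the tools were Cell Ranger and R 4.3.1 and the genome build was mm10; the version of Cell Ranger is not given in the sources used here.

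Each deposited table lists assembled contigs with, per the file headers, a read count and a UMI count, V, D, J and constant gene names, region sequences and a clonotype. These counts are whole numbers with no normalization, as deposited. All 104649 contigs carried the marks for a cell barcode, high confidence, full length and productive, as tested on the files, so unproductive contigs play no part here. Between 11666 and 14732 contigs, 754954 and 1155339 UMIs and 32395632 and 47934592 reads fell in a library. Median reads per contig ranged from 1612 to 2462, so the number of cells rather than the number of reads limits the precision of shares. A count of 3 cells is 0.0525 to 0.0654% of the paired cells of a library, which bounds cells with a listed contig (counting error only) and not cells that express a gene. All 205 gene names matched symbols of a RefSeq table of the mouse build GRCm38.p6, which is mm10, and coordinates come from it.

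A paired cell had exactly 1 heavy and 1 light contig, and 40603 cells passed. Barcodes with more than 1 heavy chain were left out as possible doublets, and no doublet caller was run. Barcodes without a heavy chain were 11.9 to 13.8% in WT and 8.23 to 10.3% in KO libraries. Isotype shares leave out cells with no constant gene (0.0654 to 0.516% of paired cells). The germline of a V gene was the most common sequence from framework 1 to framework 3 over its clones in all libraries, for genes with at least 20 clones and one length. This gave 77 of 97 IGHV genes, with the same sequence in both pools for all 77, and left out 0.661 to 1.45% of paired cells for mutation. Mutation frequency is the percent of nucleotides that differ from that germline. It can miss an allele or a mutation shared by most clones. A clone had the same IGHV, IGHJ and light V and J genes and heavy CDR3 length, joined by single linkage at a nucleotide identity of at least 0.85. Counting each clone once used clones within a library, so a clone found in several libraries was counted in each. Shares of cells in expanded clones and in the 10 largest clones, and the effective number of clones, were taken at 4585 cells per library. They were averaged over 100 seeded draws. The other clone measures used all paired cells of a library, without matching the number of cells.

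Single values were tested with an exact two-sided permutation test over the 70 assignments of 8 libraries, whose smallest p is 0.0286, called at p under 0.05 with Benjamini-Hochberg values within families. In this way 58 values were tested and 41 were called. With 1 library left out 35 assignments remain, so 1 other assignment as extreme is enough to end a call. Cell counts per IGHV and IGKV gene were tested with edgeR 4.0.16 (quasi-likelihood, library size set to paired cells or kappa cells) in R 4.3.3, with DESeq2 1.42.0 as an alternative. Low-count genes were filtered, which left 69 of 97 IGHV and 69 of 94 IGKV genes. Other steps used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, Biopython 1.88 and matplotlib 3.10.9. The tests, the groups of genes, the alternatives and the naming rule were chosen before the data were examined. The rule names the 10 most used IGHV genes and up to 15 called ones by smallest p, 6 and 10 for light V genes, all heavy constant and J genes, and the genes of the fixed groups. The groups were the 15 IGHV families, the nitrophenyl-response gene IGHV1-72 with and without lambda, the B-1-associated IGHV11-2, IGHV12-3 and IGHV7-1, the IGHV2 and IGHV5 families together, and the 3 lambda V genes; the markers were IgD, unmutated IgM or IgD, B-1 genes, very high heavy-chain UMIs and T-cell receptor contigs, which B-cell receptor primers do not amplify, so T cells were not assessed.

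Comparing the libraries showed that those of a genotype share clones as random portions of 1 pool would, so the planned tests over libraries compare 2 pools. Chosen after seeing the data were the resampling of clones (1000 draws, 95% interval), clones defined over a pool, cells with 20 to 40 heavy-chain UMIs, leaving out a free IGKV6-13 chain, the IGHG1 share of switched cells and the mutations per mutated cell. Also run, as chosen before, were TMM factors, no filter, each clone counted once, all cells with a heavy chain, at least 5 UMIs, germlines from at least 50 clones, other clone rules, no thinning, expanded clones of 5 or more cells, IgM or switched cells alone, a replicate block and leaving out each library.

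The scripts were tested on simulated data. The mutation counter found the planted number of substitutions in 2000 of 2000 cells, and the exact test called 26 of 1000 data sets without a difference. The clone rule recovered 300 of 300 clones. Each of these had its own set of V and J genes, with copies inside the identity bound. Wrong joining or splitting could therefore not occur, and the result checks only that the rule runs. For 69 IGHV genes, edgeR recovered 7 of 10 genes changed 1.5-fold and 8 of 10 changed 2-fold, with 0 of 49 unchanged genes called. For 68 IGKV genes it recovered 9 of 10 and 10 of 10, with 3 of 48 unchanged genes called. These gene counts were simulated for independent cells without clones, so recovery and false calls may differ for the real cells, which come in clones.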

Results

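Deltex-1 (Dtx1) is a ubiquitin ligase linked to Notch signalling, and the series asked how it bears on the homeostasis of germinal-centre B cells, the antigen-activated B cells that mutate and select their receptors in follicles. Germinal-centre B cells were taken from mouse spleen on day 10 after immunization, enriched with beads carrying peanut agglutinin, sorted, and loaded for droplet sequencing of paired B-cell receptors. The 8 libraries comprised 4 labelled WT (Dtx1+/+) and 4 labelled Dtx1 knockout (Dtx1-/-, KO). They held 104649 productive receptor contigs, of which 11666 to 14732 fell in each library, with 32395632 to 47934592 reads and 754954 to 1155339 unique molecular identifiers (UMIs) per library. Cells with exactly 1 heavy and 1 light chain, termed paired cells, numbered 40603, of which 18707 were WT and 21896 KO, with 4585 to 5712 per library. The targeted gene lies on chromosome 5 (120680203 to 120711867, mm10). Receptor contigs carry no Dtx1 transcript, so the knockout was not checked here.

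Libraries of one genotype shared many clonotypes, and libraries of different genotypes few. A library held 3047 to 4090 distinct paired clonotypes (heavy and light V gene and CDR3 sequence). Any 2 libraries of one genotype shared 684 to 992 of them (median 792 over 12 pairs of libraries; on average 22.9% of the clonotypes of a library), whereas 2 libraries of different genotypes shared 5 to 13 (median 8.5 over 16 pairs; 0.240%). The number of clonotypes seen in 2 or more libraries was 0.992 (WT) and 0.991 (KO) of the mean obtained when the cells of each genotype were assigned to its libraries at random. A chi-square test over the 4 libraries on IGHV gene counts was not past the threshold (WT p = 0.0886; KO p = 0.608). For clones of 20 or more cells the chi-square p was 0.682 (WT) and 0.0433 (KO), and for light V genes 0.353 (WT, or 2.86e-17 with IGKV6-13, which stood out in WT replicate 2) and 0.789 (KO). The 4 libraries of a genotype are therefore treated as 4 loadings of 1 pool of cells, and the number of mice behind each pool is not given in the labels. Every SD and p-value below measures the spread between loadings of 1 pool and compares the 2 pools, not Dtx1 genotypes across animals. Clones of each pool were also resampled. The 95% interval of the KO minus WT difference is given as the wider error for many of the values, but for none of the clone measures. It covers the sampling of clones only.

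**Figure D1:**
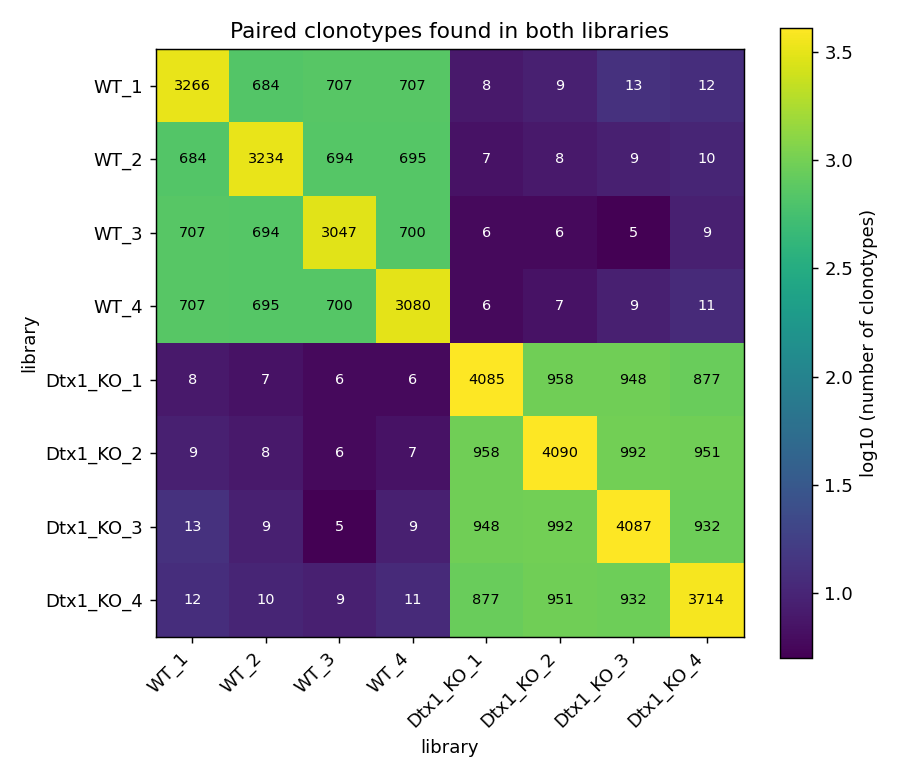
Number of identical paired clonotypes (heavy and light V gene and CDR3) found in both of 2 libraries, for all 8 libraries on both axes, with the colour on a log10 scale and the clonotypes of each library on the diagonal. Libraries of one genotype share 684 to 992 clonotypes and libraries of different genotypes share 5 to 13.

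The first comparison asked which antibody classes the cells of each pool expressed. Among switched cells, IgG1 dominated the KO pool: the IGHG1 share of class-switched cells was 78.9% ± 0.81 (SD, n = 4 loadings), against 45.3% ± 1.46 in the WT pool (clone-resampled difference 29.2 to 38.6 percentage points). As a share of all paired cells, IGHG1 was 5.27% ± 0.32 in the KO pool and 3.36% ± 0.11 in the WT pool (difference 1.31 to 2.53 percentage points). The other IgG subclasses went the opposite way. IGHG2B, the most frequent of them in WT, was 0.838% ± 0.059 in KO and 2.29% ± 0.32 in WT (difference -1.83 to -1.06). IGHG3 was 0.472% ± 0.075 in KO against 1.46% ± 0.08 in WT (difference -1.36 to -0.669), and IGHG2C was 0.0925% ± 0.036 against 0.284% ± 0.088. These constant genes lie in 1 block of chromosome 12, from IGHM (113418826 to 113422730) past IGHG3 (113357442 to 113361232), IGHG1 (113326541 to 113330523) and IGHG2B (113304314 to 113307933) to IGHG2C (113287389 to 113288932).

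Most cells of both pools were unswitched. IGHM, the constant gene of IgM, made up 93.2% ± 0.52 of KO and 91.9% ± 0.34 of WT cells, and IGHD, the constant gene of IgD, 0.122% ± 0.092 and 0.653% ± 0.157. Each difference given so far had an exact two-sided permutation p of 0.0286 (Benjamini-Hochberg value at most 0.0408 in its family), the smallest that the 70 assignments of 8 libraries allow. The total class-switched share was 6.67% ± 0.43 in KO and 7.44% ± 0.48 in WT and was not called (exact permutation p = 0.0571, adjusted p = 0.0714). It was called lower in KO with each clone counted once (-1.80 percentage points) and over all cells with a heavy chain (-0.742; exact permutation p = 0.0286 each). IGHA, the constant gene of IgA, was seen in 1 KO and 9 WT cells (exact permutation p = 0.143; called without WT replicate 3 at -0.0596 percentage points), and IGHE, that of IgE, in 0 of 21827 KO and 0 of 18656 WT cells; how well its contigs are recovered was not measured. The edgeR test on cells per class called IGHA (adjusted p = 0.0341) and not IGHM (adjusted p = 0.18). The pools differed in heavy-chain UMIs, with a median of 39.5 ± 1.91 per KO cell and 23.0 ± 1.41 per WT cell. Median light-chain UMIs were closer, at 70 to 79 in KO and 62 to 68 in WT libraries. Among cells with 20 to 40 heavy-chain UMIs, the class-switched share was higher in KO by 2.20 percentage points and that of IGHM lower (-2.20, exact permutation p = 0.0286 each). IGHD (-0.000403) and IGHG2C (-0.0350) were no longer called. IGHG1 (3.62), IGHG2B (-0.760), IGHG3 (-0.609) and the IGHG1 share of switched cells (34.9) kept their direction and call. Median UMIs differed by class, at 24.25 (WT) and 41.5 (KO) in IgM cells and 15 and 19.25 in switched cells. The window thus selects classes unequally in the 2 pools and cannot decide whether the switched and IGHM shares differ at equal heavy-chain UMIs. Medians of IgD cells (7.38 and 5.88) and IGHG2C cells (10.5 and 17.5) lay below the window, so their lost calls decide nothing. Leaving out WT replicate 2 or cells under 5 UMIs ended the call of IGHM (1.14 and 1.01), leaving out KO replicate 2 or 4 that of IGHD (-0.514 and -0.497), and leaving out any KO replicate that of IGHG2C (-0.202 to -0.178; exact permutation p = 0.0571 each).

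**Figure D2:**
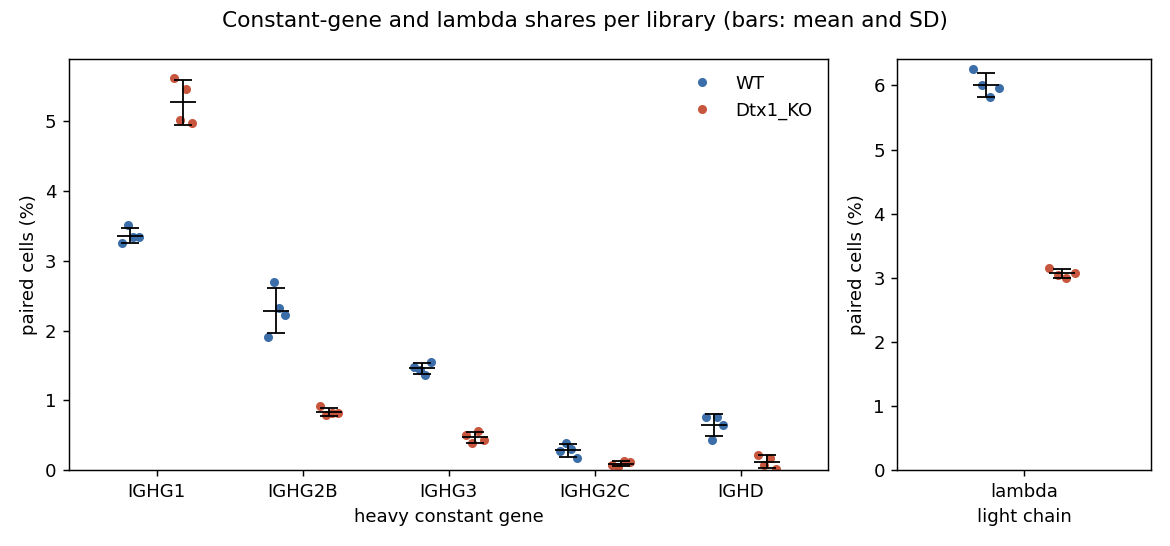
Share of paired cells (%) expressing each heavy constant gene (left) and a lambda light chain (right), with 1 point per library, 4 WT and 4 KO, and bars at the mean and SD over the loadings of a pool. IGHG1 is higher in every KO loading, and IGHG2B, IGHG3 and lambda are lower.

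The second comparison asked how far the V segments had mutated. Mutation was lower in the KO pool in both chains. Mean IGHV mutation frequency was 0.223% ± 0.016 of nucleotides in KO and 0.432% ± 0.013 in WT (SD, n = 4 loadings; clone-resampled difference -0.239 to -0.179 percentage points), a KO to WT ratio of 0.516. Mean IGKV mutation frequency was 0.109% ± 0.003 in KO and 0.214% ± 0.011 in WT (difference -0.122 to -0.0885). Cells with no IGHV mutation made up 78.1% ± 0.82 of the KO and 65.5% ± 1.04 of the WT pool (difference 10.3 to 15.1), and mutated cells carried 2.90 ± 0.11 mutations in KO and 3.56 ± 0.04 in WT. Each of these 4 differences had an exact permutation p of 0.0286, unadjusted and adjusted.

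The lower frequency was present within antibody classes. IgM cells carried 0.175% ± 0.013 in KO and 0.363% ± 0.012 in WT. IgG1 cells carried 0.856% ± 0.035 and 1.32% ± 0.05, IgG2b cells 0.900% ± 0.094 and 1.24% ± 0.03, and IgG3 cells 1.05% ± 0.12 and 1.41% ± 0.15. All switched cells together differed by -0.444 percentage points and IgM cells by -0.187 (exact permutation p = 0.0286 each). Among cells with 20 to 40 heavy-chain UMIs the difference was -0.167. The pattern of the mutations was not called different between the pools. Mutations in WRC and GYW motifs, the hotspots of activation-induced deaminase (AID), made up 72.0% ± 0.71 of KO and 72.0% ± 0.71 of WT mutations at C and G (clone-resampled difference -1.72 to 1.60 percentage points). A and T positions took 41.3% ± 0.51 and 41.6% ± 0.66 (difference -1.54 to 0.908), replacements 73.5% ± 1.01 and 74.1% ± 0.91 (difference -1.63 to 0.368), and the ratio of mutation in complementarity-determining regions (CDR) to framework regions was 2.40 ± 0.18 in KO and 2.54 ± 0.07 in WT (difference -0.278 to 0.00257; exact permutation p between 0.257 and 1.00 for these 4 measures).

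**Figure D3:**
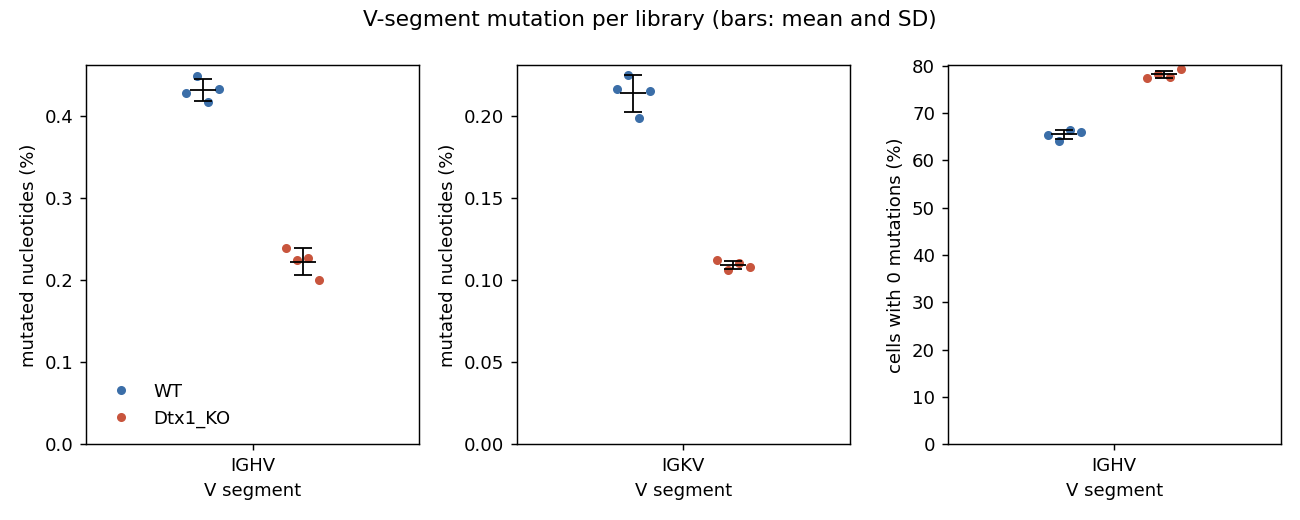
Mutated nucleotides of IGHV and IGKV segments (%) and cells with 0 IGHV mutations (%), with 1 point per library, 4 WT and 4 KO, and bars at the mean and SD over the loadings of a pool. The KO loadings lie below the WT loadings for IGHV (means 0.223 and 0.432%) and IGKV (0.109 and 0.214%), and above them for unmutated cells (78.1 and 65.5%).

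The third comparison asked how far the cells were concentrated in expanded clones. With each library thinned to 4585 cells, clones of 2 or more cells held 44.2% ± 1.12 of KO and 54.7% ± 2.92 of WT cells (SD, n = 4 loadings). The 10 largest clones held 3.62% ± 0.05 of KO and 5.78% ± 0.21 of WT cells. The effective number of clones, the exponential of the Shannon entropy of clone sizes, was 2515 ± 44 in KO and 1831 ± 81 in WT. Within clones of 3 or more cells, taken without thinning, pairs of cells differed at 0.216% ± 0.039 of IGHV nucleotides in KO and 0.435% ± 0.002 in WT. Each of these 4 differences had an exact permutation p of 0.0286 (adjusted p = 0.0357). No clone-resampled interval is given for these measures. They can depend on the number of mice in each pool, which is not given, so they describe the 2 pools only. Clones that held both unswitched and switched cells, also without thinning, made up 7.38% ± 1.33 of KO and 9.79% ± 1.08 of WT clones of 3 or more cells. This difference was not called (exact permutation p = 0.0571, adjusted p = 0.0571). With clones defined across the loadings and both pools thinned to 18707 cells, expanded clones held 64.5% (KO) and 70.7% (WT) of cells, and the effective number was 5289 and 3309, which moved the difference by more than the spread between loadings without turning it.

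The largest WT clone used IGHV1-9 with IGKV3-4 and the heavy CDR3 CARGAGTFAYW. It held 254 cells, with 62, 74, 54 and 64 in loadings 1 to 4, and 96.9% of them had no IGHV mutation. The largest KO clone used IGHV12-3 with IGKV4-91 and the heavy CDR3 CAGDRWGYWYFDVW. It held 123 cells, with 37, 22, 37 and 27 in loadings 1 to 4, and 100% of them had no IGHV mutation.

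The fourth comparison asked which heavy V genes the cells used. Of the 5 most used genes of the WT pool, 4 were called as less used in the KO pool, and IGHV9-3 was not called (4.61% of KO and 5.03% of WT cells). IGHV1-9 (chromosome 12, 114583569 to 114583862) was carried by 4.76% ± 0.49 of KO and 7.70% ± 0.36 of WT cells (SD, n = 4 loadings; log2 fold change -0.69 ± 0.06 SE, edgeR adjusted p = 2.33e-12). IGHV1-81 (115920279 to 115920572) was carried by 5.48% ± 0.38 and 7.68% ± 0.35, IGHV1-55 (115208137 to 115208527) by 3.60% ± 0.20 and 6.44% ± 0.28, and IGHV2-5 by 2.14% ± 0.30 and 4.31% ± 0.22. IGHV8-8 (115294066 to 115294362) was the most used gene of the KO pool, at 6.57% ± 0.13 against 4.18% ± 0.31 in WT (log2 fold change 0.65 ± 0.06 SE, edgeR adjusted p = 8.77e-12). IGHV1-85 (1.29% of KO and 0.406% of WT cells), IGHV2-3 and IGHV1-80 were also higher in KO, with log2 fold changes of 1.66, 1.53 and 1.18. IGHV12-3, at 1.25% in KO and 0.477% in WT, had a log2 fold change of 1.39, and its 274 KO cells fell in 12 clones, the largest of 123 cells. Its clone-resampled interval was -0.491 to 2.31 percentage points, and counting each clone once turned the difference to -0.0782.

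Of 69 IGHV genes tested on cell counts, edgeR called 41 at an adjusted p under 0.05, 25 with a higher and 16 with a lower share in KO. With trimmed-mean (TMM) factors in place of paired cells as library size, which shifted the median log2 fold change by -0.19, the calls were 17 higher and 20 lower. The clone-resampled interval excluded 0 for 18 of the 41, and 19 were called both on cells and with each clone counted once. Among the 20 genes named by the preset rule, 10 others were IGHV1-62-2 (log2 fold change -1.06), IGHV1-42 (-0.87), IGHV1-78 (-0.78), IGHV1-72 (0.90), IGHV14-2 (0.85), IGHV1-7 (0.90), IGHV1-53 (0.45), IGHV1-26 (0.37), IGHV9-3 (-0.13) and IGHV8-12 (0.11). IGHV9-3, IGHV8-12 and IGHV1-64 (0.14) were not called by edgeR (adjusted p = 0.0980, 0.284 and 0.183), though IGHV9-3 was called with TMM factors (-0.32) and IGHV1-64 without WT replicate 2 (0.23). IGHV1-26 lost its call with TMM factors (0.18). IGHV1-81, IGHV1-53, IGHV1-26, IGHV1-7 and IGHV2-3 lost theirs when each clone was counted once (-0.16, 0.17, 0.16, 0.36 and 0.63).

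**Figure D4:**
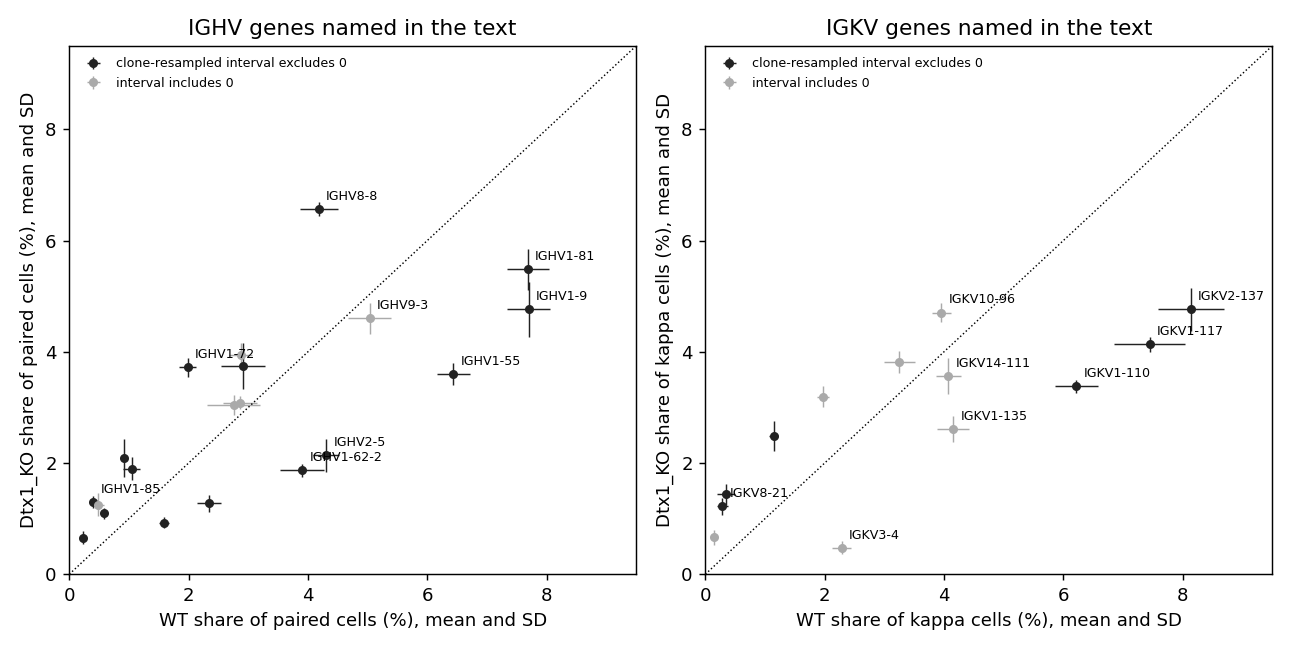
Share of paired cells using each named IGHV gene (left) and of kappa cells using each named IGKV gene (right), WT on the horizontal and KO on the vertical axis (%), with the mean and SD over 4 loadings and a dotted line of equal use. Black points are genes whose clone-resampled interval excludes 0; IGHV1-9, IGHV1-81 and IGHV1-55 lie below the line, and IGHV8-8 lies above it.

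Light-chain use differed too. The most used kappa genes of the WT pool, IGKV2-137 (chromosome 6, 67555636 to 67556216), IGKV1-117 (68121091 to 68121825) and IGKV1-110 (68270527 to 68271265), were carried by 8.14% ± 0.55, 7.45% ± 0.60 and 6.22% ± 0.36 of its kappa cells. In the KO pool they were carried by 4.76% ± 0.38, 4.13% ± 0.13 and 3.38% ± 0.12 (SD, n = 4 loadings; log2 fold changes -0.77, -0.85 and -0.88; edgeR adjusted p = 7.98e-09, 1.52e-09 and 9.46e-10). IGKV8-21 (2.09), IGKV8-19 (2.04), IGKV5-48 (1.12) and IGKV12-44 (0.70) were higher in KO on the log2 scale, and the clone-resampled interval excluded 0 for the first 3 of them. IGKV3-4 (-2.26) and IGKV8-34 (2.15) had the largest fold changes of the named genes, with intervals that included 0 (-5.24 to 0.0346 and -0.0707 to 1.42 percentage points); the largest WT clone carries IGKV3-4. IGKV1-135 (-0.67) was called on cells and not with each clone counted once (-0.096).

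Of 69 IGKV genes tested, edgeR called 50, 32 higher and 18 lower in KO, and with TMM factors, which shifted the median by -0.24, 23 higher and 23 lower. The interval excluded 0 for 20 of them. IGKV10-96 (0.25), IGKV14-111 (-0.19) and IGKV6-15 (0.23) were called by edgeR (adjusted p = 0.000966, 0.0263 and 0.00733) with intervals that included 0. IGKV10-96 lost its call with TMM factors (0.0093) or each clone counted once (0.057), and IGKV14-111 when WT replicate 1 or 3 or KO replicate 2, 3 or 4 was left out (-0.19 to -0.14). IGKV6-15 lost its call with every cell with a heavy chain (0.15) and turned with TMM factors (-0.0080) and with each clone counted once (-0.14). Lambda light chains, the minor light-chain class of the mouse, were carried by 3.07% ± 0.07 of KO and 6.01% ± 0.18 of WT cells (exact permutation p = 0.0286, adjusted p = 0.0408; clone-resampled difference -4.65 to -1.62). IGLV1 was carried by 2.26% ± 0.05 and 4.07% ± 0.20, IGLV3 by 0.142% ± 0.040 and 1.00% ± 0.14, and IGLV2 by 0.668% ± 0.063 and 0.936% ± 0.047, the last with an interval of -0.641 to 0.0594.

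Of 24 fixed groups of V genes, 15 were called on loadings (exact permutation p = 0.0286, adjusted p = 0.0457 each), and 5 of these had a clone-resampled interval that excluded 0: the IGHV8 family (9.67% ± 0.13 in KO, 7.11% ± 0.25 in WT), the IGHV3 family (0.0542% ± 0.024 and 0.166% ± 0.023), IGHV1-72 (3.72% ± 0.16 and 1.99% ± 0.14), IGLV1 and IGLV3. The IGHV3 family was not called among all cells with a heavy chain (-0.0773, exact permutation p = 0.0571). IGHV1-72 paired with lambda, the pair that dominates nitrophenyl responses in C57BL/6 mice, made up 0.0551% ± 0.039 of KO and 0.0643% ± 0.036 of WT cells (exact permutation p = 0.657). The IGHV1 family (63.3% and 66.8%), IGHV4 (0.302% and 0.545%), IGHV5 (4.80% and 4.00%), IGHV7 (1.30% and 0.813%), IGHV11 with its single gene IGHV11-2 (0.167% and 0.0159%), IGHV12 with IGHV12-3 and IGHV15 (0.0598% and 0.445%) were called with intervals that included 0. Leaving out any KO replicate ended the call for IGHV4 (-0.256 to -0.224) and IGHV15 (-0.391 to -0.377), any WT replicate that for IGHV11 (0.145 to 0.160), and WT replicate 1, 3 or 4 that for IGHV7 (0.467 to 0.479). Counting each clone once ended the calls of IGHV4 (-0.216), IGHV5 (0.494), IGHV7 (0.0311), IGHV11 (0.0212) and IGHV15 (-0.000475) and turned IGHV12 (-0.0782), with exact permutation p between 0.0571 and 1.00. The IGHV2 (7.47% and 8.29%), IGHV6 (1.34% and 1.42%), IGHV9 (5.33% and 5.56%), IGHV10 (1.18% and 0.925%), IGHV13 (0.177% and 0.138%) and IGHV14 (3.55% and 3.28%) families, IGHV7-1 (0.0821% and 0.107%) and the D-proximal IGHV2 and IGHV5 families together (12.3% and 12.3%) were not called. IGHV2 (-1.0) and IGHV10 (0.329) were called without WT replicate 2, and IGHV2 (-0.866) and IGHV6 (-0.432) with each clone counted once.

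Heavy J genes and CDR3 length were compared last among the receptor features. IGHJ3 was used by 24.4% ± 0.89 of KO and 28.4% ± 0.40 of WT cells and IGHJ1 by 18.5% ± 0.38 and 15.9% ± 0.32 (SD, n = 4 loadings; exact permutation p = 0.0286, adjusted p = 0.0381), with clone-resampled differences of -7.84 to -0.561 and 0.0457 to 5.12 percentage points. IGHJ4 (26.9% ± 1.09 and 25.4% ± 0.31) was called with an interval of -1.55 to 4.30, and leaving out any WT replicate ended its call (1.41 to 1.64, exact permutation p = 0.0857). IGHJ2 (30.2% ± 0.17 and 30.3% ± 0.61) was not called (exact permutation p = 0.857). The mean heavy CDR3 was 14.45 ± 0.03 amino acids in KO and 14.32 ± 0.02 in WT (exact permutation p = 0.0286), with an interval of -0.0714 to 0.320. Counting each clone once turned the difference for IGHJ1 (-0.448, exact permutation p = 0.257) and CDR3 length (-0.0358, p = 0.200), and turned and called that for IGHJ2 (1.36, p = 0.0286).

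Markers of other cells that the sort could hold also differed between the pools. Unmutated IgM or IgD cells, the type that naive B cells would show, made up 77.1% ± 0.76 of KO and 65.0% ± 1.04 of WT cells. Unmutated cells were most frequent in large clones: 93.0% (KO) and 84.9% (WT) of cells in clones of 10 or more cells had no IGHV mutation. In single-cell clones 68.6% and 54.9% had none. The share is therefore not taken as a share of naive cells. IGHD, the marker of naive follicular cells, was lower in KO over all cells. It was not called at 20 to 40 UMIs (-0.000403). That window lies above the median UMIs of IgD cells (7.38 in WT, 5.88 in KO) and so cannot decide whether IGHD differs. Cells with IGHV11-2 or IGHV12-3, genes associated with B-1 cells, made up 1.42% ± 0.21 of KO and 0.493% ± 0.086 of WT cells, with an interval of -0.342 to 2.50. Cells with more than 10 times the median heavy-chain UMIs of their library, as plasmablasts would have, made up 0.258% ± 0.087 of KO and 0.480% ± 0.082 of WT cells. Leaving out any WT replicate ended that call (-0.245 to -0.189). The median was 39.5 in KO and 23.0 in WT libraries, so the cut-off was higher in KO and the shares are not at 1 absolute threshold. No T-cell receptor contig was listed, which says nothing about T cells, since B-cell receptors were amplified. Barcodes with more than 1 productive heavy chain, from doublets or allelic inclusion, made up 3.99% ± 0.37 in KO and 3.22% ± 0.34 in WT, and KO libraries held 5474 ± 295 paired cells against 4677 ± 114 (exact permutation p = 0.0286 for each difference named here). Leaving out any library but WT replicate 2 ended the call for extra heavy chains (0.619 to 0.891 percentage points), and leaving out any WT replicate that for paired cells (767 to 852, exact permutation p = 0.0571 each). Every KO library (5045 to 5712) still held more paired cells than any WT library (4585 to 4842), so that lost call comes from the few assignments left (35).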

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

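In this part the test with 20 to 40 UMIs was chosen after the result was seen; the comparison of switched cells alone was chosen beforehand, but the bound it was held to was set after.

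In 6 of 178 sets of 4 libraries (3.37%; chance gives about 5%), 1 library stood apart from the other 3. Among the KO libraries IGHA was seen in replicate 2 alone, at 0.0176% of cells, which is 1 cell. IGHV1-72 was at 3.97% in KO replicate 3 and at 3.63 to 3.64% in the other KO libraries. Cells with IGHV11-2 or IGHV12-3 were at 1.10% in KO replicate 2 against 1.52 to 1.54%. Pairwise IGHV differences within clones were 0.438% in WT replicate 1 against 0.434% in the others. IGHV1-81 was at 7.15% in WT replicate 4 against 7.85 to 7.87%, and IGHV2-5 at 1.70% in KO replicate 1 against 2.26 to 2.34%.

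The lower IGHV mutation frequency of the KO pool (0.223% against 0.432%) was weighed against 2 explanations. More unmutated unswitched cells beside a wholly unchanged mutated fraction would leave switched cells alike, and these differed by -0.444 percentage points. This goes against that extreme form alone. A larger unmutated share in KO (78.1% against 65.5%) remains part of the difference, beside fewer mutations per mutated cell (2.90 against 3.56). Sequence errors in the WT contigs, which rest on fewer UMIs, would shrink the difference among cells with 20 to 40 UMIs, where 0.797 of it remained (-0.167 of -0.209 percentage points). What stays open is the genotype rather than another difference between the 2 pools, such as the mice, the response to immunization or the sort: with 1 pool per genotype these cannot be told apart. A difference by genotype is a hypothesis that separate mice would test.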

How the results depend on the processing

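The alternatives with 20 to 40 UMIs, resampled clones, clones defined over a pool and the omitted IGKV6-13 chain were chosen after the results were seen; values below are KO minus WT.

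The lower mutation and clonality of the KO pool and its higher IGHG1 and lower lambda shares kept direction and call in every tested alternative run on them except the replicate block. The class-switched share turned at 20 to 40 UMIs (2.20 percentage points), with IGHM (-2.20), and was called with all cells with a heavy chain (-0.742) or each clone counted once (-1.80). That window selects IgM and switched cells unequally in the 2 pools, so these 2 turns cannot decide whether switching differs at equal heavy-chain UMIs. Counting each clone once also turned CDR3 length (-0.0358), IGHJ1 (-0.448), IGHJ2 (1.36), the IGHV9 (0.0506), IGHV10 (-0.0366) and IGHV12 (-0.0782, the gene IGHV12-3) families, and the log2 fold changes of IGHV1-64 (-0.11) and IGKV6-15 (-0.14). It lowered the calls from 41 to 20 IGHV genes (11 higher, 9 lower), from 50 to 31 IGKV genes (20 and 11) and from 15 to 9 gene groups. Resampled clones left 18 IGHV genes (10 and 8), 20 IGKV genes (16 and 4), 5 groups, and CDR3 length at 0.132 with an interval that included 0. TMM factors turned IGHV8-12 (-0.078), IGHV1-64 (-0.042) and IGKV6-15 (-0.0080). Without the free IGKV6-13 chain 51 IGKV genes were called (33 and 18). DESeq2 called 39 IGHV genes (19 higher, 20 lower) and 40 IGKV genes (19 and 21). The AID hotspot share, with a difference near 0, turned with all cells (-0.0616), germlines from 50 clones (-0.0493) and resampled clones (-0.0525). The IGHV2 and IGHV5 families together turned with all cells (0.402) and at least 5 UMIs (0.00303). Clones over a pool moved the expanded share (-6.18) and the effective number (1980). Leaving out each library gave -0.340 to 0.198 for the hotspot share, -0.321 to 0.120 for IGHJ2, -0.0266 to 0.00573 for IGHV1-72 with lambda, -0.159 to 0.176 for the IGHV2 and IGHV5 families, 718 to 940 for paired cells and 0.619 to 0.894 for barcodes with more than 1 heavy chain; call or direction changed in at least 1 case for each. The cause of these changes was not tested. Counting each clone once lowers the weight of large clones but does not remove it, since a clone found in several loadings counts in each.

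Replicate numbers were also used as a replicate block. Deviations of same-numbered libraries did not correlate (IGHV -0.146 to -0.0705, IGKV -0.207 to 0.0361, none highest with its own number), so the numbers are not taken as pairs. The sign-flip test of 4 pairs cannot go below an exact p of 0.125 and so calls nothing: 0 isotype, 0 IGHJ, 0 gene-group and 0 marker values, nor lambda (-2.94), IGHV (-0.209) and IGKV (-0.104) mutation, unmutated cells (12.7), CDR3 length (0.131), expanded clones (-10.5), the 10 largest clones (-2.16), effective number (684), within-clone differences (-0.220), extra heavy chains (0.767), paired cells (797) or UMIs (16.5). The edgeR block called 41 IGHV and 48 IGKV genes. The alternative with germline V segments from a reference genome was not run, since no genome was used here. Among constant genes, IGHA, IGHE and IGHG2C rest on the fewest cells, with 9, 0 and 53 cells in WT and 1, 0 and 20 in KO.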

Other observations

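All tests in this part were chosen after the results were seen, except the 2 on clone size, whose bounds were set before.

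Single replacements recurred across independent clones of the most used genes. Positions are counted from 1 at the first residue of framework 1, and the genes were chosen after their values were seen. In IGHV1-81, S31N was found in 95 of 499 WT clones (19.0%, exact 95% interval 15.7 to 22.8) and 25 of 685 KO clones (3.65%, 2.38 to 5.34). Among clones with any IGHV1-81 mutation the shares were 29.0% (24.1 to 34.2) and 14.2% (9.41 to 20.3). In IGHV1-9, S55R was found in 88 of 424 WT clones (20.8%) and 32 of 430 KO clones (7.44%), or 30.1% (24.9 to 35.8) and 15.6% (10.9 to 21.3) of mutated clones, and N59K in 57 and 29 clones, or 19.5% (15.1 to 24.5) and 14.2% (9.68 to 19.7) of mutated clones, with intervals that overlap. Of the 12 most recurrent replacements, 10 were higher in WT among mutated clones, including S54N of IGHV1-42 (33.7% and 22.4%) and S57R of IGHV1-9 (17.5% and 12.7%), with S59N of IGHV1-26 the closest (17.2% and 16.5%). V37I and T28I of IGHV1-9 were higher in KO (13.2% and 10.2%) than in WT (8.90% and 7.88%). Mutated KO cells carried fewer mutations (2.90 against 3.56), so shares of mutated clones were not compared at equal mutation number. A clone was counted if any of its cells carried the replacement, and clone size was not matched between the pools. In WT, 94.0% of cells with S31N and 95.5% of those with S55R carried other IGHV mutations too. Germline codons were AGC for S31 and AGT for S55. The intervals cover counting of clones only.

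The shared clonotypes of a genotype's libraries fit one pool of cells loaded on 4 channels: the lower of the 2 ratios to random assignment was 0.991. Index hopping or shared barcodes would give the same heavy CDR3 to barcodes found in 2 libraries, which held for 0% of 427 such barcodes. Rearrangements common to all mice would also be shared between genotypes, where sharing was 0.0105 of that within a genotype. Whether a pool held 1 mouse or several stays open.

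Clones of 10 or more cells carried fewer IGHV mutations than single-cell clones in both pools. In them, 84.9% (WT) and 93.0% (KO) of cells had none, against 54.9% and 68.6% of single-cell clones. The relation was not steady in WT, where clones of 2 to 4 cells had the lowest unmutated share (44.5%). Sequence errors in cells of small clones, which have fewer UMIs, would remove this at 20 to 40 UMIs, where the smaller of the 2 differences was still 23.3 percentage points. Unrelated cells joined by the clone rule stay open: 79.99% of cells in such clones had their clone's most common pair of CDR3 sequences, just under the bound of 80 set beforehand. A clone that mutates also leaves the rule's reach more easily, which was not tested, so no biological explanation is offered.

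Both pools shared 35 of 22101 clonotypes. Their mean heavy CDR3 was 11.7 amino acids, against 14.4 over all clonotypes (p = 0.0001 against 10000 random sets of 35 clonotypes, a permutation test, the smallest p these can give), a difference of -2.69 that fits short junctions arising repeatedly. Of the 35, 7 paired IGHV2-2 with IGKV6-23 and 3 paired IGHV1-76 with IGKV14-111. Other routes to clonotypes in both pools were not tested, and barcodes were compared within a genotype only.

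A kappa chain with IGKV6-13 and the CDR3 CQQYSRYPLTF was listed in 90 cells, all in WT replicate 2, beside 88 heavy CDR3s. Its median was 4 UMIs, against 65 for other light chains of that library, and the heavy chains beside it had a median of 1 UMI against 22. IGKV6-13 cells numbered 10, 105, 8 and 6 in WT replicates 1 to 4. With this gene, light V counts differed over the WT libraries (chi-square p = 2.86e-17), and without it the chi-square p was 0.353.

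Splits of the 8 libraries tested whether chance assignment gives as many called genes. Of 35 splits, 1, the real one, called 41 IGHV genes and 1, the real one, called 50 IGKV genes, and the highest count of any other split was 0 for both. Loadings of 1 pool would give this for any difference between 2 pools, so the splits cannot decide whether the calls of single genes arose by chance.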
